A study of Homo sapiens with 12 samples.

How the data were processed

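Per the labels, RNA of JEKO-1 cells was taken after 48 h with DMSO, choline salicylate (CS), KPT-330 or both drugs, with an extraction kit for fixed tissue, and made into poly(A)-selected libraries with a kit that does not mark the strand. Per the series design text, Illumina reads were aligned to hg38 with STAR inside a modified MAP-RSeq workflow, and the authors deposited gene counts on Ensembl version 78. The program that counted the reads, its strand setting and the tool versions are not given in the sources used here, so reads from overlapping genes on opposite strands cannot be told apart. Per the same text, the study used edgeR with TMM normalization and a negative binomial generalized linear model, called genes at a Benjamini-Hochberg adjusted p of 0.05 or less and an absolute log2 fold change over 2, and compared each treatment with control and CS with a drug written KPT-300, read here as KPT-330.

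The deposited counts are whole numbers for 64253 genes in 12 libraries, which were assigned to 4 groups of 3 by the labels; each value column belonged to 1 library. Of the gene identifiers, 56105 were also in the GENCODE 44 reference, 99.92% of them on the same chromosome with overlapping spans, and GC content was known for 97.0% of the tested genes. Some gene names in the table had been turned into dates by a spreadsheet (1-Mar), and identifiers were used to join tables.

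Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr by group, libraries were scaled by TMM, and the robust quasi-likelihood F-test (two-sided) was run with all 12 libraries in 1 fit with group as the only term, which left 8 residual degrees of freedom. The 7 contrasts were each treatment against DMSO, CS against KPT-330, the combination against each single drug, and the interaction of both drugs. Adjusted p-values are Benjamini-Hochberg over the tested genes of each contrast. CPM used TMM-scaled library sizes, and log2 CPM for the principal components and list tests used a prior count of 2.

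There were 34 gene lists, and 32 had at least 3 tested members; the epithelial and erythroid lists did not. EPCAM and KRT8 were the only tested epithelial members, with at most 116 and 62 reads in any library, and no erythroid gene had more than 3. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over 224 tests, of which 106 passed. With an estimated correlation 58 passed, and the text gives that adjusted p where the call was lost.

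The comparisons, lists, tests, thresholds and most alternatives were fixed before the data were examined, as was the rule for naming genes. Per comparison, the rule took the 8 genes with the highest and the 8 with the lowest log2 fold change that had an adjusted p of 0.05 or less, a mean of at least 5 CPM in the higher group, and no overlap between the libraries compared (a condition not used for the interaction); between 3 and 3 libraries chance alone gives no overlap in 10% of splits. Clone-based names, LINC, MIR, SNOR, RNU and HIST names and immunoglobulin or T cell receptor segments were passed over, and comparisons treated in less detail name the first 4 of each. From each list described it took up to 4 members that passed, by size of change, and up to 2 that did not. It always took XPO1, CDKN1A, MDM2, CCND1, SOX11, MYC, BRCA1, CHEK1, PTGS2 and CCNE2. Some genes that the rule took, and a list, are not reported here. Genes with 3 or fewer reads over a group are given as a ratio of reads with a 95% exact interval, and a group at 0 reads by the 95% lower limit of the ratio; intervals and limits cover counting error only.

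The alternatives chosen then were no filter, a stricter filter (1 CPM in at least 3 libraries), DESeq2 size factors, scaling by library size alone, DESeq2 1.42.0, the edgeR likelihood ratio test, limma voom, the replicate number as a block, the compared groups alone, each library left out in turn, and for lists an estimated correlation. After the data were seen, a GC correction (lowess, span 0.3) within groups or over all libraries was added, as was a run without the lowest-GC-slope library of DMSO, CS and KPT-330+CS. Where a library was left out, the spread was taken from all groups together. Lists were not run with the stricter filter, DESeq2 itself, the likelihood ratio test, limma voom or the compared groups alone.

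The steps were tested on simulated data with 200 genes changed. Counts were drawn gene by gene, with the same spread in all groups and no GC trend between libraries. Far more genes were called in the real data, so the shares below need not hold there. For KPT-330 against DMSO (19039 genes) 56.5%, 90.0% and 100% of genes changed by a fold of 1.5, 2 and 4 were called, with 14 unchanged genes called. For the interaction (19033 genes) the shares were 35.5%, 74.3% and 97.1%, again with 14 unchanged genes called. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.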

Results

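RNA was sequenced from JEKO-1, a human mantle cell lymphoma line, after 48 h in 4 conditions with 3 libraries each. The conditions were DMSO (the solvent control), choline salicylate (CS, a salicylate salt), KPT-330 (selinexor, an inhibitor of the nuclear export receptor XPO1, also called CRM1), and KPT-330 together with CS. The study asked whether a salicylate adds to the effect of CRM1 inhibition, with an eye to S phase and to the repair of DNA damage. The concentrations used for these libraries are not given in the sources used here. Nor is it given whether the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Total counts were 50939785, 44144749 and 45219838 for DMSO replicates 1 to 3, 44871267, 49787540 and 59490178 for CS, 50654498, 48439949 and 54865536 for KPT-330, and 46252572, 35325563 and 54426896 for KPT-330 with CS. Of 64253 genes in the table, 28113 had no count in any library and 19460 were tested. Levels are given as CPM (counts scaled to the size of each library, mean ± SD of 3 libraries) and differences as edgeR log2 fold changes ± SE. The test itself gives no SE. It was derived as the absolute log2 fold change divided by the square root of the F statistic, and is approximate for genes with few reads.

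The first principal component held 52.4% of the variance and placed all 6 libraries with KPT-330 on one side and the other 6 on the opposite side. The second component held 18.1% and placed the KPT-330 libraries apart from those given both drugs. Libraries of one group also differed in how counts depended on GC content. The slope of log2 counts per 10 GC points was 0.21 ± 0.02 in KPT-330, -0.12 ± 0.20 in DMSO, -0.09 ± 0.14 in CS and 0.00 ± 0.14 in KPT-330 with CS (SD, n = 3). Within DMSO, CS and the combination, libraries with a higher slope also lay higher on the second component. For DMSO it went from 25.9 in replicate 1 (slope 0.087) to -16.1 in replicate 3 (slope -0.314). The second component was thus not tied to treatment alone. The biological coefficient of variation was 2.88% within KPT-330, against 15.5% in DMSO, 11.9% in CS and 10.8% in the combination. Mitochondrial ribosomal RNA took 2.61% ± 0.12 of the counts in the combination, against 1.15% ± 0.10 in DMSO, 1.18% ± 0.06 in CS and 1.44% ± 0.03 in KPT-330.

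**Figure D1:**
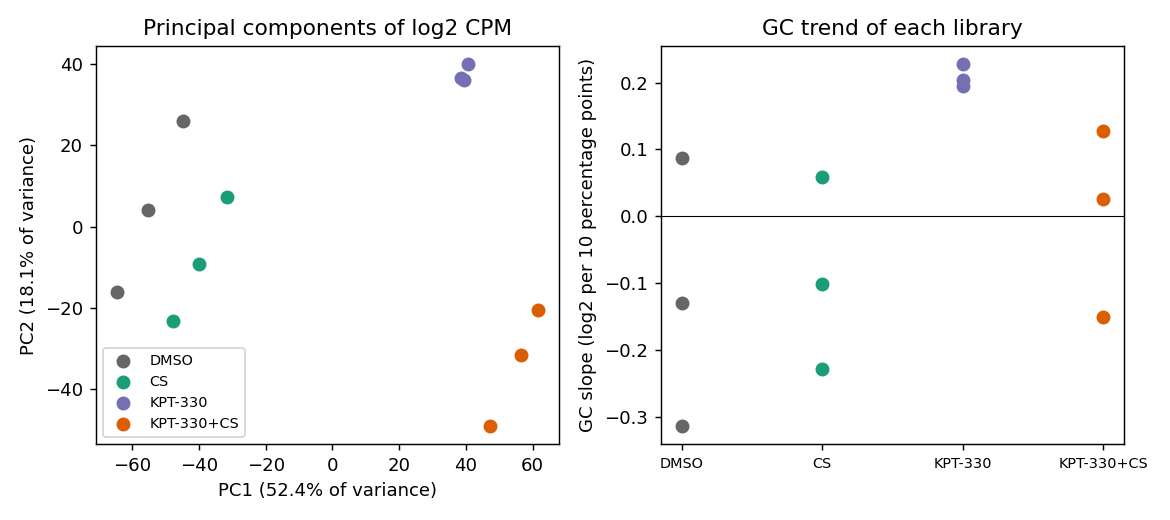
Left, each of the 12 libraries on the first and second principal components of log2 CPM (52.4% and 18.1% of the variance); right, the slope of log2 counts per 10 points of GC content in each library, by group. Libraries with and without KPT-330 separate on the first component, and the slopes of the 3 KPT-330 libraries (0.20 to 0.23) lie closer together than those of any other group.

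The comparison of KPT-330 with DMSO asks what the inhibitor did alone. NGFR, which encodes a nerve growth factor receptor (ENSG00000064300, chromosome 17, 49495293 to 49515017 of hg38), rose from 0.0529 ± 0.0491 to 10.8 ± 0.58 CPM, a log2 fold change of 7.59 ± 0.39. MDK, which encodes the growth factor midkine (ENSG00000110492, chromosome 11, 46380756 to 46383837), rose by 7.02 ± 0.30 on the log2 scale. The next highest were LIX1, SLC2A4RG, CAPN5, MTSS1L, GOLGA7B and FBXO32, between 6.23 ± 0.28 and 3.45 ± 0.24; LIX1 overlaps another annotated gene, and these counts cannot tell the genes apart. LRRC32 (ENSG00000137507, chromosome 11, 76657524 to 76670747) fell from 5.04 ± 1.01 to 0.0680 ± 0.0169 CPM. PIR (ENSG00000087842, chromosome X, 15384799 to 15493564) fell (log2 fold change -3.03 ± 0.09), as did the cystine transporter gene SLC7A11 (-2.80 ± 0.14) and the anti-apoptotic BCL2 family member BCL2A1 (-2.77 ± 0.12). SSPN (which overlaps BHLHE41), IFI44L, BMP3 and the fatty acid receptor gene CD36 followed, between -2.48 ± 0.17 and -2.27 ± 0.11. In all 16 genes the 3 KPT-330 libraries lay outside the range of the 3 DMSO libraries, as the naming rule required. Their adjusted p lay between 1.73e-10 and 2.52e-07 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. XPO1 itself, the target of the drug (ENSG00000082898, chromosome 2, 61477849 to 61538626), rose from 845 ± 87.7 to 1575 ± 38.0 CPM (log2 fold change 0.90 ± 0.07, adjusted p = 7.64e-07 by edgeR).

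Genes of G2/M and mitosis fell with KPT-330. Of 32 tested members, 31 were lower and 0 higher (31 lower and 1 higher when adjusted over the list alone), with a median log2 fold change of -0.92 and adjusted p = 8.03e-19 by camera, a competitive gene set test. The proliferation marker gene MKI67 went from 1176 ± 77.4 to 428 ± 7.14 CPM, CENPA fell (-1.45 ± 0.06) and CENPE (-1.36 ± 0.08), while CDC25B stood at 0.30 ± 0.13 (adjusted p = 0.0739 by edgeR). Of replication and G1/S genes 17 of 43 were lower and 7 higher, the same numbers when adjusted over the list alone, with a median of -0.03. Against other genes the list did not pass (camera adjusted p = 0.201), and the self-contained test fry of limma called it lower (adjusted p = 2.78e-05). Cyclin A gene CCNA2 fell (-0.93 ± 0.09), POLD1 stood at 0.95 ± 0.34 and CCNE2 rose by 0.98 ± 0.11, whereas TK1 stood at 0.36 ± 0.23 without passing. Among homologous recombination and Fanconi anaemia genes, 14 of 37 were lower and 3 higher (13 and 3 when adjusted over the list alone), with a median of -0.04 (camera adjusted p = 0.188). BRCA2 fell (-0.73 ± 0.08). BRCA1 stood at -0.10 ± 0.07, not past the threshold, and CHEK1, a checkpoint kinase gene, fell (-0.23 ± 0.06).

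NF-kappaB targets were lower as a group, 18 of 26 lower and 3 higher both over all genes and adjusted over the list alone (median -0.52, camera adjusted p = 0.000276). The cytokine gene TNF had 38 reads over the DMSO libraries and 3 over the KPT-330 libraries, a ratio of 15.5 with a 95% counting interval of 4.92 to 78.5, and the chemokine gene CCL4 fell (-2.19 ± 0.22). RELB, a subunit gene of NF-kappaB, stood at 0.28 ± 0.15 without passing. The unfolded protein response genes of the endoplasmic reticulum fell, 17 of 20 lower and 1 higher (18 lower and 1 higher adjusted over the list alone; median -0.69, camera adjusted p = 7.52e-09), led by the chaperone gene HSPA5 at -1.47 ± 0.06, XBP1 at -1.31 ± 0.09 and HSP90B1 at -1.17 ± 0.07. Targets of NRF2, a regulator of the response to oxidative stress, were lower for 13 of 17 members and higher for 1, also adjusted over the list alone (median -0.50, camera adjusted p = 5.8e-05). HMOX1 was at -2.22 ± 0.36 and PGD at -0.77 ± 0.08. Cholesterol synthesis and uptake genes were lower for 15 of 23 and higher for 1, also adjusted over the list alone (median -0.47, camera adjusted p = 6.87e-06). HMGCS1 fell (-1.01 ± 0.08). Nuclear-encoded respiratory chain genes (20 of 27 lower, 1 higher, also adjusted over the list alone; median -0.38, camera adjusted p = 5.38e-07) were lower too, with NDUFB3 at -0.72 ± 0.09. Cytosolic ribosomal protein genes were lower for 47 of 79 and higher for 1 (48 and 1 adjusted over the list alone; median -0.26, camera adjusted p = 1.37e-07), with RPSA at -0.62 ± 0.05. Ribosomal protein genes have near-identical copies in the genome, so single members are uncertain.

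Nuclear export and import genes were lower for 12 of 22 members and higher for 2 (12 and 3 adjusted over the list alone; median -0.25, camera adjusted p = 0.00194, and adjusted p = 0.0684 with an estimated correlation). XPO1 was one of those higher, and the importin genes KPNA2 (-1.64 ± 0.05) and KPNB1 (-0.64 ± 0.07) fell. B cell identity genes were higher for 14 of 25 and lower for 5 (16 and 6 adjusted over the list alone; median 0.50, camera adjusted p = 0.0126, and adjusted p = 0.25 with an estimated correlation). The B cell surface receptor gene CD22 rose from 14.0 ± 0.91 to 44.7 ± 0.74 CPM and CD72 by 1.06 ± 0.08. The list of T cell markers was higher for 7 of 7 members, also adjusted over the list alone (median 1.39, camera adjusted p = 0.00463, and adjusted p = 0.0851 with an estimated correlation), at low levels: CD7 reached 0.685 ± 0.0995 CPM and CD8A 1.09 ± 0.21. TP53INP1 and BBC3 rose by 2.47 ± 0.17 and 2.35 ± 0.25. CDKN1A stood at 0.31 ± 0.14, MDM2 at 0.00 ± 0.08, CCND1 at 0.34 ± 0.22 and SOX11 at -0.05 ± 0.06, none past the threshold. MYC rose by 0.74 ± 0.08. MDM2 overlaps CPM, CHEK1 overlaps STT3A, and CCNE2 and TP53INP1 overlap NDUFAF6, so these counts may hold reads of either gene. PTGS2, which encodes a cyclooxygenase, had 0 reads in each of the 12 libraries, and 0 reads over a group has a 95% upper bound of 3.

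In total 4815 genes were higher and 4631 lower with KPT-330 at an adjusted p of 0.05 or less, and 588 also passed the study's limit of a log2 fold change beyond 2 (523 higher, 65 lower). Scaled by library size alone the split was 6651 higher and 2905 lower, with the median of all genes shifted by 0.16. The KPT-330 libraries were also those with the highest GC slopes. The calls of CHEK1 and POLD1 depended on single libraries and on the fit. CHEK1 stood at -0.06 scaled by library size alone (adjusted p = 0.317 by edgeR), -0.17 without DMSO replicate 3 and -0.20 without KPT-330 replicate 3. POLD1 stood between 0.69 (without DMSO replicate 3) and 1.01 (without KPT-330 replicate 1), not called without any library but DMSO replicate 1. It was at 0.36 with GC correction over all libraries (adjusted p = 0.0965 by edgeR) and stood at 0.68 without the lowest-GC-slope libraries (adjusted p = 0.144), and it was not called with DESeq2 (adjusted p = 0.0563) or with no filter (adjusted p = 0.17). Of the genes given here as not passing, CDKN1A, MDM2, CCND1, BRCA1, CDC25B, RELB and TK1 passed in some alternative, CCND1 at 0.63 without DMSO replicate 1 (adjusted p = 0.0446) and CDKN1A at 0.46 with library size alone (adjusted p = 0.0228).

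CS alone, compared with DMSO, changed fewer genes than KPT-330 did. Transfer RNA genes of the mitochondrial genome were at both ends of its ranking. MT-TF (ENSG00000210049, mitochondrial chromosome, 577 to 647) fell from 16.1 ± 1.38 to 2.57 ± 0.44 CPM and MT-TD fell (log2 fold change -2.20 ± 0.14), while MT-TR rose from 1.86 ± 0.40 to 6.57 ± 0.69 CPM and MT-TI by 1.12 ± 0.09. Such genes have near-identical nuclear copies. They are also short, and the libraries were selected for poly(A), so these counts need not reflect the level of mature transfer RNA. Also higher were SNX29P2, DERL3, GNG7, GVINP1, CD22 and SYNPO, between 1.37 ± 0.19 and 1.16 ± 0.12; CD22 (ENSG00000012124, chromosome 19, 35319261 to 35347355) reached 31.4 ± 2.31 CPM. SNX29P2 is listed under 2 identifiers, and DERL3 overlaps SMARCB1. Also lower were the phosphatase gene DUSP5, BBOX1 (the last enzyme of carnitine synthesis), BZRAP1, the tyrosine kinase gene FGR, PLXND1 and CD36, between -1.61 ± 0.10 and -1.21 ± 0.10. BBOX1 (ENSG00000129151, chromosome 11, 27040725 to 27127809) went from 77.4 ± 7.45 to 29.7 ± 0.71 CPM. All 16 had adjusted p between 9.34e-07 and 0.00423 by edgeR. The 3 CS and the 3 DMSO libraries did not overlap, as the naming rule required.

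Replication-dependent histone genes fell with CS: 29 of 48 tested members were lower and 0 higher (38 lower adjusted over the list alone), with a median of -0.88 (camera adjusted p = 2.47e-26). HIST1H2BC went from 12.5 ± 0.62 to 4.15 ± 0.37 CPM, and HIST1H2AD (-1.58 ± 0.31) and HIST1H2BM (-1.54 ± 0.32) fell, while HIST1H1B stood at -1.32 ± 0.51 without passing. HIST1H3A had 19 reads over DMSO and 3 over CS, a ratio of 7.27 with a 95% counting interval of 2.14 to 38.3. Histone genes have near-identical copies, and their messages mostly lack the poly(A) tail by which the libraries were selected. ATF4 and integrated stress response genes rose, 10 of 29 higher and 2 lower (15 and 2 adjusted over the list alone; median 0.31, camera adjusted p = 4.1e-07), with CHAC1, a glutathione-degrading enzyme gene, at 2.54 ± 0.39, the glycine transporter gene SLC6A9 at 2.49 ± 0.62 and STC2 at 1.05 ± 0.16, against 1.09 ± 0.33 for VLDLR, which did not pass. Heat shock genes were lower for 9 of 16 (12 adjusted over the list alone; median -0.23, camera adjusted p = 4.22e-07), among them the chaperonin gene HSPD1 at -0.44 ± 0.06, from 2304 ± 174 to 1697 ± 82.1 CPM. Unfolded protein response genes were lower for 8 of 20 and higher for 1 (10 and 2 adjusted over the list alone; median -0.19, camera adjusted p = 1e-04), with HSP90B1 at -0.57 ± 0.07 and HSPA5 at -0.53 ± 0.06.

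MYC target and ribosome biogenesis genes were lower for 9 of 26 (11 adjusted over the list alone; median -0.22, camera adjusted p = 3.17e-06), with NOP56 at -0.33 ± 0.04. Respiratory chain genes of the nucleus were lower for 8 of 27 (12 adjusted over the list alone; median -0.14, camera adjusted p = 1.1e-07). Interferon-stimulated genes were lower for 7 of 26 and higher for 1 (11 and 1 adjusted over the list alone; median -0.25, camera adjusted p = 0.00107). IFIT2 was at -1.12 ± 0.32, IFI44 at -0.96 ± 0.20 and IFIT3 at -0.91 ± 0.18. Replication and G1/S genes were lower for 7 of 43 (11 adjusted over the list alone; median -0.08, camera adjusted p = 0.000276). CDC25A was at -0.35 ± 0.05. G2/M genes were lower for 6 of 32 (11 adjusted over the list alone; median -0.15, camera adjusted p = 2.15e-06, and adjusted p = 0.232 with an estimated correlation). BUB1 was at -0.38 ± 0.07. B cell identity genes were higher for 9 of 25 and lower for 1, also adjusted over the list alone (median 0.17, camera adjusted p = 1.58e-06), with the low-affinity IgE receptor gene FCER2 at 1.28 ± 0.29 and BANK1 at 0.58 ± 0.09. T cell markers were lower for 1 of 7 (2 adjusted over the list alone; median -0.76, camera adjusted p = 0.00832, and adjusted p = 0.101 with an estimated correlation). Myeloid markers were lower for 2 of 5 (3 adjusted over the list alone; median -0.73, camera adjusted p = 0.0272, and adjusted p = 0.101 with an estimated correlation), a call that both GC corrections also ended (adjusted p = 0.127 within groups and 0.111 over all libraries) and that leaving out DMSO replicate 1 took to 0.397. CDKN1A, which encodes the cell cycle inhibitor p21, rose by 0.63 ± 0.14 (adjusted p = 0.0129 by edgeR). XPO1, MDM2, CCND1, SOX11, MYC, BRCA1, CHEK1 and CCNE2 did not pass, with log2 fold changes between -0.12 ± 0.06 for CHEK1 and 0.20 ± 0.07 for BRCA1.

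CS raised 731 genes and lowered 998, of which 28 passed the study's limit (17 higher, 11 lower). These counts depended on the fit and on single libraries. In the fit of all 12 libraries the biological coefficient of variation was 11.1%, below 15.5% within DMSO and 11.9% within CS. The tighter KPT-330 libraries (2.88%) thus lent precision to this comparison. With only the DMSO and CS libraries in the fit the genes higher and lower were 159 and 90. Scaled by library size alone they were 1365 and 714. Without DMSO replicate 2 they were 402 and 415 and without CS replicate 2, 358 and 402, while the lower genes were 1792 without DMSO replicate 1, 583 without DMSO replicate 3 and 360 without CS replicate 3. The naming rule took 48 genes that were called with CS, not all of them printed here. Of these, 22 kept the call in every alternative that tested them. The call was lost for 25 with only the DMSO and CS libraries in the fit, and none turned sign. Of the genes printed here, those 25 include DERL3, BZRAP1, PLXND1, HIST1H2AD, HIST1H2BM, SLC6A9, IFIT2, IFIT3, IFI44, FCER2, BUB1 and CDKN1A (adjusted p between 0.0543 and 0.194 by edgeR). Leaving out a single library ended the calls of CDKN1A (0.63 without DMSO replicate 2, 0.60 without CS replicate 2), SLC6A9 (2.40 and 2.21 without DMSO replicates 1 and 2, 2.12 without CS replicate 2), IFI44 (-0.74 without DMSO replicate 3, -0.79 without CS replicate 3) and FCER2 (1.11 without CS replicate 3). IFIT2 stood between -0.82 (without DMSO replicate 3) and -1.26 (without DMSO replicate 2), not called without either of these or CS replicate 2 or 3, and HIST1H3A was not called without any library but DMSO replicate 1, between -2.20 (without DMSO replicate 2) and -2.81 (without CS replicate 1). IFIT2 was also not called with no filter, DESeq2 size factors, library size alone, DESeq2, limma voom, the replicate block or without the lowest-GC-slope libraries (adjusted p between 0.0505 and 0.0952), nor was HIST1H3A with DESeq2, limma voom, the replicate block or without those libraries. Of the genes given here as not passing, XPO1, SOX11, MYC, BRCA1, CHEK1 and VLDLR passed in some alternative. The gene lists were not tested in the fit of the DMSO and CS libraries alone.

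The combination was compared with DMSO to show what both drugs did together. NGFR rose to 25.8 ± 4.64 CPM (log2 fold change 8.85 ± 0.38), and MDK, FBXO32 (a ubiquitin ligase subunit gene), BEX2, CAPN5, C1orf54, TP53INP1 and SIGLEC17P rose by between 5.83 ± 0.30 and 4.0 ± 0.28. TP53INP1 (ENSG00000164938, chromosome 8, 94925972 to 94949411), a gene of autophagy and cell death, went from 0.886 ± 0.228 to 17.6 ± 1.4 CPM. C1orf54 overlaps APH1A, and SIGLEC17P is a pseudogene with close relatives. LRRC32 fell (-6.62 ± 0.26). CD36 (ENSG00000135218, chromosome 7, 80369575 to 80679277) fell from 35.5 ± 3.26 to 0.997 ± 0.189 CPM (-5.16 ± 0.13). SIRPA, BBOX1, ABCA6, TMPRSS15, the immediate-early gene EGR1 and BCL2A1 followed, between -3.49 ± 0.20 and -2.86 ± 0.12. All 16 genes had adjusted p between 6.87e-12 and 5.55e-08 by edgeR, with the 3 libraries of each group apart, as the naming rule required.

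Replication and G1/S genes fell in the combination. Of 43 members, 40 were lower and 0 higher, also adjusted over the list alone, with a median of -0.66 (camera adjusted p = 2.48e-15). CCNA2 went from 289 ± 34.8 to 88.0 ± 7.88 CPM, the ribonucleotide reductase gene RRM2 from 420 ± 40.1 to 130 ± 9.24, CDC45, a replicative helicase component gene, fell (-1.5 ± 0.08) and CDC25A (-1.33 ± 0.05), whereas POLD1 stood at -0.27 ± 0.34 and CCNE2 at 0.12 ± 0.11 without passing. G2/M and mitosis genes fell for 31 of 32, also adjusted over the list alone (median -1.55, camera adjusted p = 1.33e-22). MKI67 was at -2.12 ± 0.06, or 270 ± 12.1 CPM, CENPA at -2.04 ± 0.07 and BIRC5, which encodes survivin, at -1.92 ± 0.11. CDC25B stood at -0.18 ± 0.13.

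Of 5 repair and checkpoint lists 4 were lower by the preset test, and none of these 4 calls held with an estimated correlation. The other, base excision repair and PARP genes, had 5 of 21 higher and 6 lower, also adjusted over the list alone (median -0.04, camera adjusted p = 0.699). Homologous recombination and Fanconi anaemia genes were lower for 29 of 37 and higher for 4 (30 and 4 adjusted over the list alone; median -0.49, camera adjusted p = 2.54e-07, and adjusted p = 0.198 with an estimated correlation). POLQ fell (-1.01 ± 0.08), FANCD2 (-0.91 ± 0.07), BLM (-0.90 ± 0.08), EXO1 (-0.88 ± 0.06) and BRCA1 (-0.48 ± 0.07), while BRIP1 stood at -0.18 ± 0.08. DNA damage checkpoint genes were lower for 14 of 20 and higher for 3, also adjusted over the list alone (median -0.33, camera adjusted p = 0.00491, and adjusted p = 0.268 with an estimated correlation). CLSPN was at -1.73 ± 0.08, WEE1 at -1.19 ± 0.08, H2AFX at -1.03 ± 0.23 and CHEK1 at -0.63 ± 0.07. For non-homologous end joining 7 of 13 were lower and 1 higher, also adjusted over the list alone (median -0.34, camera adjusted p = 0.0189, and adjusted p = 0.0977 with an estimated correlation), with XRCC5, which encodes Ku80, at -0.95 ± 0.07 and PRKDC at -0.71 ± 0.05. For mismatch repair 7 of 12 were lower and 1 higher, also adjusted over the list alone (median -0.45, camera adjusted p = 0.00498, and adjusted p = 0.311 with an estimated correlation). PCNA was at -1.0 ± 0.05. The counting strand is not given in the sources used here.

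NF-kappaB targets fell for 19 of 26 with 0 higher, also adjusted over the list alone (median -0.64, camera adjusted p = 6.31e-07). The chemokine gene CCL22 had 392 reads over DMSO and 2 over the combination, a ratio of 215 with a 95% counting interval of 59.3 to 1785. TNF had 38 reads and 0, a ratio with a 95% lower counting limit of 10.8, and EBI3 51 and 2, a ratio of 28.0 with a 95% counting interval of 7.37 to 238. IL10 fell (-3.20 ± 0.38), and NFKB2 stood at 0.37 ± 0.17 without passing. ATF4 and integrated stress response genes were higher for 19 of 29 and lower for 4, also adjusted over the list alone (median 0.56, camera adjusted p = 0.02, and adjusted p = 0.198 with an estimated correlation). SLC6A9 was at 2.62 ± 0.62 and CHAC1 at 2.12 ± 0.40; SLC7A11, the largest exception, fell (-1.87 ± 0.13). Corrected for GC content over all libraries, this list's adjusted p was 0.0565 by camera. NRF2 targets were lower for 14 of 17 (median -0.46, camera adjusted p = 2.91e-05), also adjusted over the list alone, and HMOX1 was at -5.23 ± 0.53. Unfolded protein response genes were lower for 15 of 20 with 2 higher (median -0.85, camera adjusted p = 3.63e-06), also adjusted over the list alone, with HYOU1 at -1.36 ± 0.10. MYC target and ribosome biogenesis genes were lower for 22 of 26 and higher for 2 (23 and 2 adjusted over the list alone; median -0.66, camera adjusted p = 8.27e-07). MRTO4 was at -0.94 ± 0.05, while MYC rose by 1.30 ± 0.08, from 200 ± 19.5 to 490 ± 30.6 CPM. Nuclear export and import genes were lower for 16 of 22 and higher for 2 (median -0.51, camera adjusted p = 1.12e-05, the same counts adjusted over the list alone). KPNA2 was at -2.65 ± 0.06, and XPO1 rose by 0.86 ± 0.07. Heat shock genes were lower for 12 of 16 with 1 higher (median -0.54, camera adjusted p = 3.35e-05), also adjusted over the list alone, with HSPA8 at -1.82 ± 0.08. CDKN1A stood at 0.28 ± 0.14, MDM2 at 0.02 ± 0.08, CCND1 at 0.10 ± 0.22 and SOX11 at 0.14 ± 0.06, none past the threshold.

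The combination raised 5711 genes and lowered 5095, of which 848 passed the study's limit (690 higher, 158 lower). Scaled by library size alone, the split was 7606 higher and 3363 lower, with the median of all genes shifted by 0.18. The 55 genes taken by the naming rule and called in this comparison, not all of them printed here, kept the call in every alternative that tested them. A gene removed by a filter was not tested there. Of the genes given here as not passing, CDKN1A, MDM2, SOX11, CCNE2, POLD1, CDC25B, BRIP1 and NFKB2 passed in some alternative. CDC25B did at -0.34 with GC correction over all libraries (adjusted p = 1.39e-07 by edgeR). SOX11 did in 7, at 0.33 with library size alone (adjusted p = 5.39e-05) and 0.17 with the compared groups alone (adjusted p = 0.0455).

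**Figure D2:**
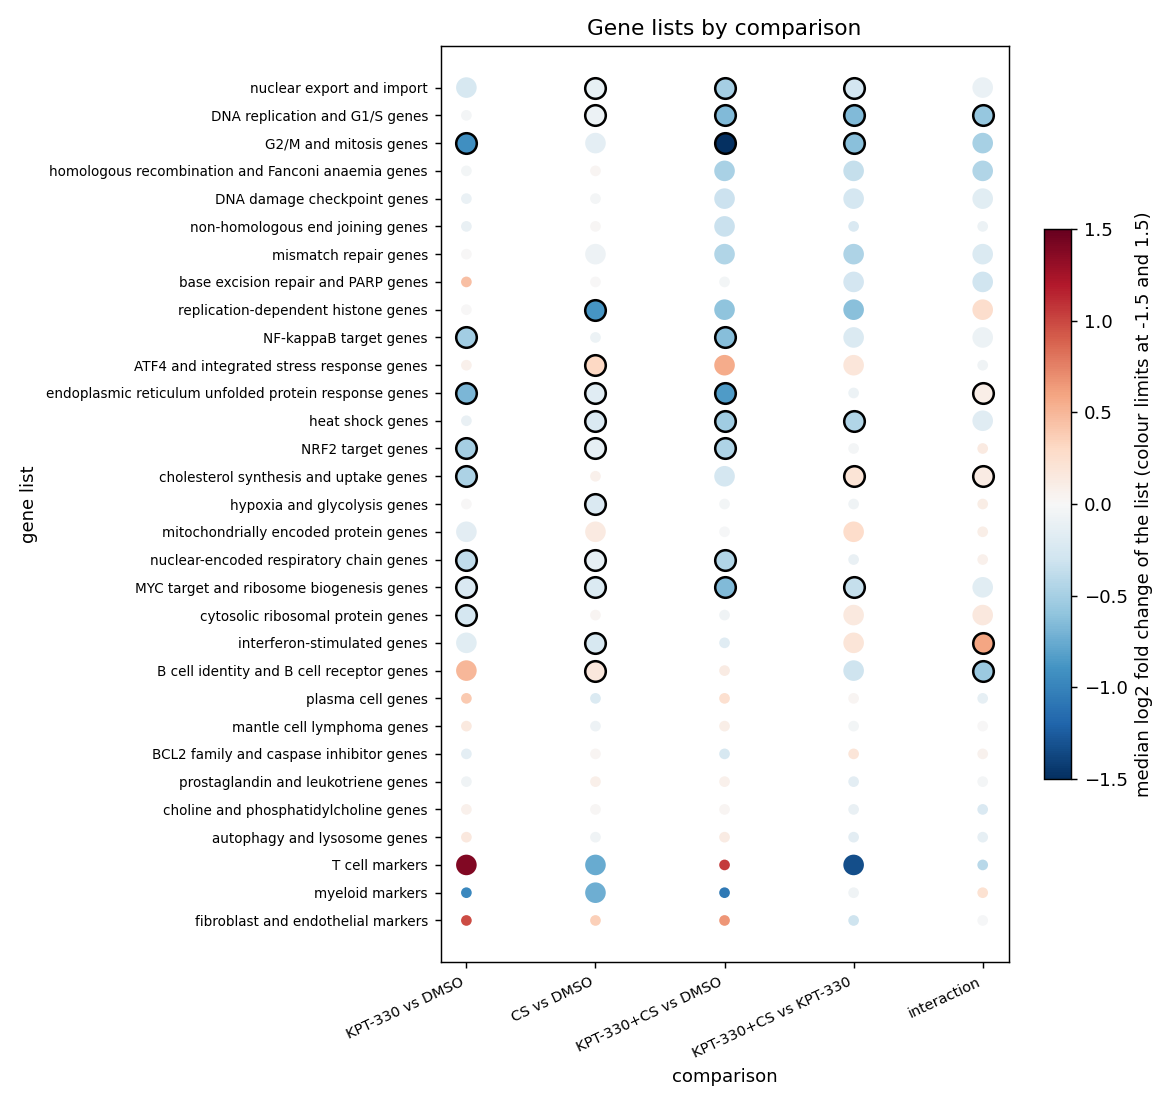
Median log2 fold change of the tested members of each gene list (vertical axis) in each comparison (horizontal axis), with colour limited to -1.5 to 1.5. A large dot marks an adjusted p of 0.05 or less by camera with the preset correlation and a black ring one that also held with an estimated correlation. The G2/M list was lower by the preset test in every comparison shown. Its median was -0.92 with KPT-330, -0.15 with CS and -1.55 with both. It was -0.62 for the combination against KPT-330 and -0.50 for the interaction. Its calls with CS and for the interaction were lost with an estimated correlation. The replication list had a median of -0.03 with KPT-330 and -0.08 with CS, against -0.66 with both.

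The combination was then compared with KPT-330 alone, which asks what CS added in cells given KPT-330. Every tested replication and G1/S gene was lower: 43 of 43, also adjusted over the list alone, with a median of -0.66 (camera adjusted p = 3.11e-26). The call of the member POLD1 depended on the fit. It was lost with no filter (adjusted p = 0.0999 by edgeR) and without the lowest-GC-slope libraries (adjusted p = 0.067). Leaving out KPT-330+CS replicate 3 also ended it (adjusted p = 0.0574). CDC45 (ENSG00000093009, chromosome 22, 19479459 to 19520612) went from 108 ± 2.23 to 41.2 ± 1.62 CPM (-1.39 ± 0.08, adjusted p = 1.05e-07 by edgeR) and RRM2 (ENSG00000171848, chromosome 2, 10122328 to 10131419) from 324 ± 9.34 to 130 ± 9.24 CPM. UHRF1 fell (-1.23 ± 0.15) and CCNE2 (-0.86 ± 0.11). G2/M and mitosis genes were lower for 29 of 32 with 0 higher, also adjusted over the list alone (median -0.62, camera adjusted p = 5.22e-19). BIRC5 was at -1.19 ± 0.11 and the mitotic kinase gene PLK1 at -1.17 ± 0.11. Homologous recombination and Fanconi anaemia genes were lower for 25 of 37 and higher for 1, also adjusted over the list alone (median -0.36, camera adjusted p = 5.72e-09, and adjusted p = 0.147 with an estimated correlation). XRCC3 fell (-0.96 ± 0.19), EXO1 (-0.89 ± 0.06), FANCA (-0.81 ± 0.09) and BRCA1 (ENSG00000012048, chromosome 17, 43044295 to 43125483; -0.38 ± 0.07). Checkpoint genes were lower for 10 of 20 and higher for 3, also adjusted over the list alone (median -0.26, camera adjusted p = 0.0126, and adjusted p = 0.32 with an estimated correlation). H2AFX was at -1.13 ± 0.23, CLSPN at -0.97 ± 0.08 and CHEK1 at -0.40 ± 0.06.

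The highest genes of this comparison were FAM9B, MT-TR, RGS1, TP53INP1, DLGAP1-AS1, GABARAPL1, JAKMIP2 and OAS1, between 2.40 ± 0.14 and 1.66 ± 0.06. OAS1, an interferon-induced antiviral gene, had 16.5 ± 0.84 CPM with KPT-330 and 51.9 ± 1.49 with both drugs, against 67.6 ± 2.27 in DMSO. The lowest were BBOX1, CD36, ABCA6, SLIT2, LIX1, SLITRK6, PIGR and the adhesion gene CADM1, between -3.66 ± 0.08 and -2.17 ± 0.07; BBOX1 went from 87.4 ± 0.08 to 6.88 ± 0.56 CPM. Adjusted p for these 16 lay between 1.92e-11 and 1.1e-05 by edgeR. The 3 libraries of each group did not overlap, as the naming rule required. Heat shock genes were lower for 12 of 16 (14 adjusted over the list alone; median -0.45, camera adjusted p = 1.05e-07), with HSPH1 at -0.69 ± 0.07. MYC target and ribosome biogenesis genes were lower for 20 of 26 with 2 higher (21 and 2 adjusted over the list alone; median -0.36, camera adjusted p = 9.34e-07), while MYC rose by 0.55 ± 0.07. Cholesterol synthesis and uptake genes were higher for 11 of 23 (11 higher and 1 lower adjusted over the list alone; median 0.21, camera adjusted p = 0.00312). MSMO1 was at 0.82 ± 0.08 and HMGCS1 at 0.75 ± 0.07. ATF4 and integrated stress response genes were higher for 11 of 29 and lower for 2, also adjusted over the list alone (median 0.18, camera adjusted p = 0.00207, and adjusted p = 0.0972 with an estimated correlation). ATF3 was at 1.5 ± 0.21 and VLDLR at 1.43 ± 0.29. B cell identity genes were lower for 13 of 25 and higher for 3 (14 and 3 adjusted over the list alone; median -0.31, camera adjusted p = 0.0011, and adjusted p = 0.143 with an estimated correlation). The transcription factor gene SPIB was at -1.23 ± 0.09. Over all genes, 3836 were higher and 3475 lower, and 166 passed the study's limit (63 higher, 103 lower). The lower genes numbered 5379 with each library corrected for GC content within its group.

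**Figure D3:**
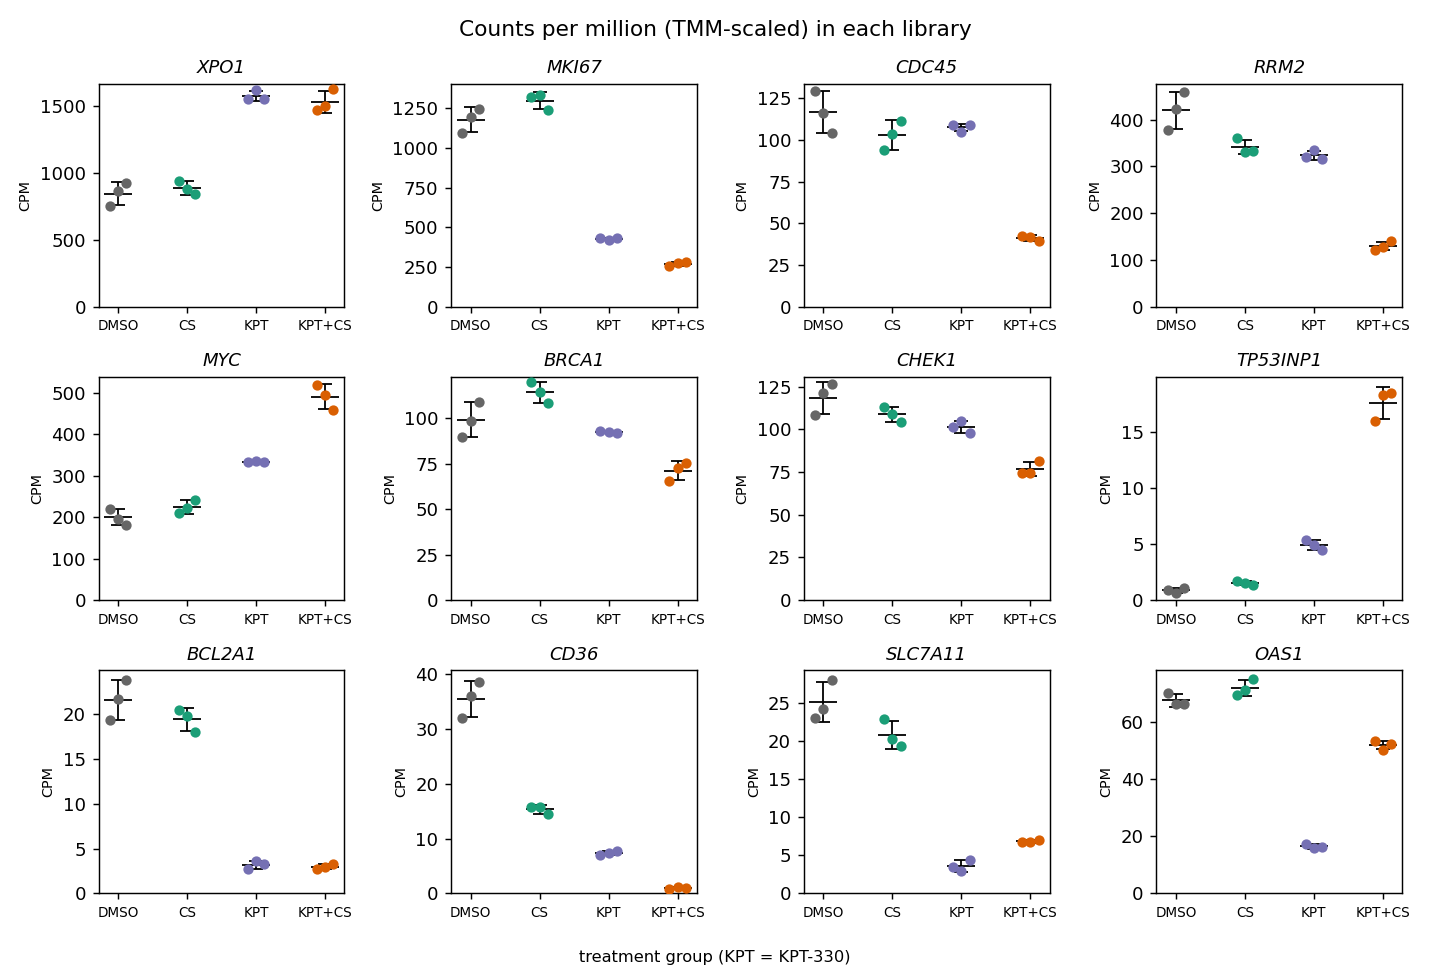
Level in CPM (vertical axis, starting at 0) of 12 genes in each library, by group, with the mean and SD of 3 libraries; the genes were chosen for the plot after their values were seen. CDC45 was at 117, 103 and 108 CPM in DMSO, CS and KPT-330 and at 41.2 with both drugs, and XPO1 was at 845 and 889 CPM without KPT-330 and at 1575 and 1532 with it.

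Whether CS acted differently in the presence of KPT-330 was tested as an interaction, the CS effect with KPT-330 minus the CS effect with DMSO. The replication and G1/S list was lower in this contrast for 36 of 43 genes and higher for 0 (41 and 0 adjusted over the list alone; median -0.59, camera adjusted p = 3.31e-27). CDC45 stood at -1.21 ± 0.11 and E2F1, a G1/S transcription factor gene, at -1.07 ± 0.18. G2/M genes were lower for 23 of 32 (27 adjusted over the list alone; median -0.50, camera adjusted p = 1.31e-16, and adjusted p = 0.0512 with an estimated correlation). AURKB was at -1.10 ± 0.18. Homologous recombination and Fanconi anaemia genes were lower for 20 of 37 and higher for 1 (23 and 1 adjusted over the list alone; median -0.45, camera adjusted p = 2.61e-11, and adjusted p = 0.101 with an estimated correlation). RAD54L stood at -0.82 ± 0.08 and BRCA1 at -0.58 ± 0.10, while CHEK1 stood at -0.28 ± 0.09 without passing. CHEK1 passed in 6 alternatives, at -0.42 with GC correction over all libraries (adjusted p = 1.85e-07) and -0.32 with library size alone (adjusted p = 0.0118). Interferon-stimulated genes were higher for 11 of 26 and lower for 0 (15 and 0 adjusted over the list alone; median 0.59, camera adjusted p = 8.47e-07). IFIT2 was at 3.61 ± 0.43 and IFIT3 at 1.92 ± 0.26. B cell identity genes were lower for 13 of 25 and higher for 0 (16 and 0 adjusted over the list alone; median -0.55, camera adjusted p = 1.22e-09). FCER2 was at -2.10 ± 0.41. A gene below 0 in this contrast need not lie below its level in DMSO. RGS1, a regulator of G protein signalling, was at 3.07 ± 0.42 CPM in DMSO, 1.21 ± 0.01 in CS, 1.36 ± 0.14 in KPT-330 and 5.26 ± 0.37 with both. Those genes named here had adjusted p between 8.84e-07 and 0.00477 by edgeR, apart from CHEK1.

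The interaction was called for 1565 genes above 0 and 1288 below, and 148 passed the study's limit (54 above, 94 below). Corrected for GC content over all libraries, the split was 2162 above and 2959 below. Leaving out DMSO replicate 1 gave 2639 and 2072. Leaving out any of 8 others moved the genes above 0 to between 885 (KPT-330 replicate 3) and 988 (KPT-330+CS replicate 2). They were 900 for DMSO replicate 2, 944 and 925 for CS replicates 2 and 3, 920 and 965 for KPT-330 replicates 1 and 2 and 959 for KPT-330+CS replicate 3. Genes below 0 were 853 without CS replicate 2 and 828 without KPT-330 replicate 3. Across the 19460 genes, the CS effect measured with DMSO and that measured with KPT-330 used separate libraries; their log2 fold changes had Pearson's r = 0.24 and Spearman's rho = 0.30 over genes, which are not independent replicates. Of the 1729 genes called with CS alone, 79.3% had the same sign in the other comparison.

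**Figure D4:**
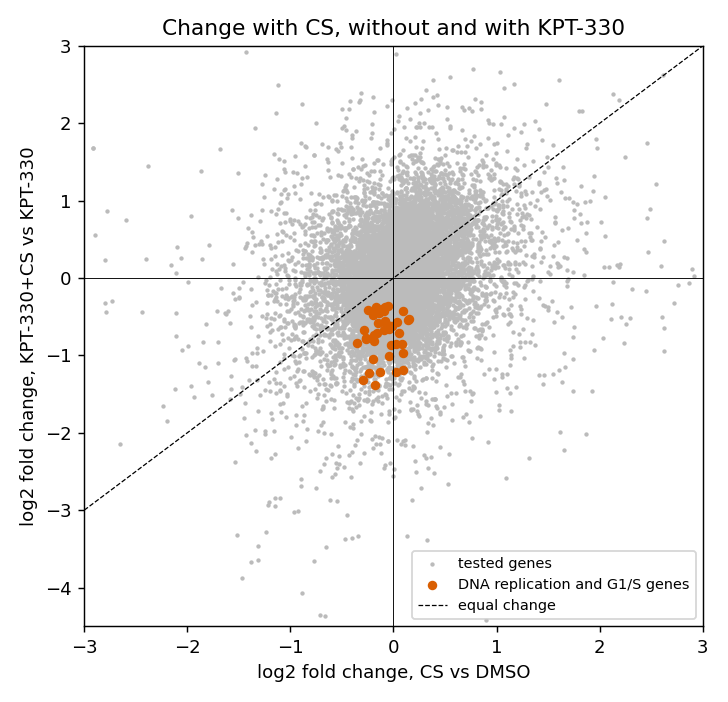
Log2 fold change of each of 19460 tested genes with CS against DMSO (horizontal axis) and with KPT-330+CS against KPT-330 (vertical axis), with the 43 replication and G1/S genes marked; 34 genes lie outside the axes. The marked genes lie near 0 on the horizontal axis (median -0.08) and below 0 on the vertical axis (median -0.66).

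CS and KPT-330 were also compared directly, as the study did. PIR, BCL2A1, SLC7A11 and BMP3 were higher in CS than in KPT-330 by between 3.07 ± 0.09 and 2.25 ± 0.10, and NGFR, LIX1, MDK and SLC2A4RG lower by between -6.55 ± 0.34 and -4.05 ± 0.31. G2/M genes were higher in CS for 27 of 32 (29 adjusted over the list alone; median 0.69, camera adjusted p = 1.76e-18). Cholesterol genes were higher for 16 of 23 with 1 lower (17 and 1 adjusted over the list alone; median 0.46, camera adjusted p = 9.35e-08). T cell markers were lower for 7 of 7, also adjusted over the list alone (median -2.28, camera adjusted p = 0.000111). In all 3925 genes were higher in CS and 4400 lower, 520 past the study's limit (53 higher, 467 lower); scaled by library size alone the split was 2926 and 5489. The combination against CS alone, which shows what KPT-330 added to CS, had NGFR, CAPN5, MDK and FBXO32 highest (7.81 ± 0.33 to 4.20 ± 0.23) and CD36, ABCA6, PIR and TMPRSS15 lowest (-3.95 ± 0.13 to -2.79 ± 0.07). G2/M genes were lower for 31 of 32 (32 adjusted over the list alone; median -1.38, camera adjusted p = 3.11e-26) and replication genes for 39 of 43, also adjusted over the list alone (median -0.59, camera adjusted p = 5.46e-17). Of the tested genes 5081 were higher and 4216 lower, 583 past the study's limit (474 higher, 109 lower), and by library size alone 6549 and 3029, with the median of all genes shifted by 0.12. The 16 genes named here had adjusted p between 4.91e-11 and 5.76e-07 by edgeR. The libraries compared did not overlap, as the naming rule required.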

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

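In this part the GC corrections were chosen after the results were seen; so was the scaling test, while the interaction and the splits of the libraries were planned. The results here were picked out because the effect of CS differed between cells with and without KPT-330 by the interaction test of edgeR: 1565 genes were above 0, 1288 below, and 148 past the study's limit.

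Among replication and G1/S genes (list median -0.59) the interaction log2 fold change was -1.28 ± 0.33 for TK1, -1.21 ± 0.11 for CDC45, -1.08 ± 0.33 for CDT1, -1.07 ± 0.18 for E2F1 and -0.84 ± 0.16 for CCNE2. In the G2/M list (median -0.50) AURKB was at -1.10 ± 0.18 and BIRC5 at -1.06 ± 0.16, and in the homologous recombination list (median -0.45) XRCC3 was at -1.02 ± 0.26, POLQ at -0.83 ± 0.11, RAD54L at -0.82 ± 0.08, FANCA at -0.80 ± 0.13 and BRCA1 at -0.58 ± 0.10. Interferon-stimulated genes (median 0.59) included IFIT2 at 3.61 ± 0.43, IFIT3 at 1.92 ± 0.26 and IFI6 at 1.67 ± 0.39. B cell identity genes (median -0.55) included FCER2 at -2.10 ± 0.41, CD22 at -1.40 ± 0.10 and SPIB at -1.25 ± 0.13. CD22 was at 14.0 CPM in DMSO, 31.4 in CS, 44.7 in KPT-330 and 37.8 with both drugs. Its value below 0 thus reflects a rise smaller than the sum of the single-drug changes, not a level below DMSO. Among the genes furthest above 0 were RGS1 at 3.28 ± 0.19, FAM9B at 2.71 ± 0.21, GABARAPL1 at 2.26 ± 0.17, DLGAP1-AS1 at 2.03 ± 0.21, MT-TW at 1.70 ± 0.22, OAS1 at 1.57 ± 0.08 and DDIT4 at 1.55 ± 0.15, and MYC stood at 0.38 ± 0.11. Those furthest below 0 were SLITRK6 at -2.81 ± 0.24, MDK at -2.80 ± 0.45, LIX1 at -2.58 ± 0.53, PIGR at -2.37 ± 0.26, BBOX1 at -2.28 ± 0.11, SNX29P2 at -2.23 ± 0.27, RGS19 at -2.16 ± 0.32 and STARD4-AS1 at -2.14 ± 0.17, which overlaps STARD4. Without KPT-330, MDK was at 0.132 CPM in DMSO and 0.416 in CS, and LIX1 at 0.111 and 0.130. The CS effect with DMSO that enters their values thus rests on few reads.

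Leaving out 1 library ended 5 of these calls, and 4 of the 5 also ended in other alternatives. LIX1 stood at -2.17 without CS replicate 3. MYC stood between 0.33 (without CS replicate 1) and 0.39 (without DMSO replicate 2), and its call also ended without CS replicate 2, any KPT-330 replicate, or KPT-330+CS replicate 1 or 2. TK1 stood between -1.08 (without CS replicate 3) and -1.32 (without CS replicate 2), with its call also ended without DMSO replicate 2 or 3 or KPT-330 replicate 3. CDT1 stood between -0.86 (without CS replicate 3) and -1.12 (without CS replicate 2), with its call also ended without DMSO replicate 2 or 3, any KPT-330 replicate, or KPT-330+CS replicate 2 or 3. XRCC3 stood between -0.87 (without DMSO replicate 3) and -1.04 (without CS replicate 2), with its call also ended without DMSO replicate 2, KPT-330 replicate 2 or KPT-330+CS replicate 3. By edgeR, MYC was also not called with the replicate block (adjusted p = 0.0614), library size alone (adjusted p = 0.0728) or GC correction over all libraries (adjusted p = 0.0641). CDT1 was not called with the replicate block (adjusted p = 0.0758), the stricter filter (adjusted p = 0.0586), no filter (adjusted p = 0.212), library size alone (adjusted p = 0.084) or without the lowest-GC-slope libraries (adjusted p = 0.0612). TK1 was not called with no filter (adjusted p = 0.139) or without those libraries (adjusted p = 0.0777), nor XRCC3 with no filter (adjusted p = 0.126).

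Replication and G1/S genes fell more with CS in cells given KPT-330 than in cells given DMSO. A trend of counts with GC content between the libraries would shrink the list's median interaction once removed, and after correction over all libraries it was -0.65. A shift of the scaling by a few abundant genes would move the median of all tested genes by about as much as the list, and between library size alone and TMM that median moved by -0.038. Both values argue against these as the whole cause. A different response to CS in the presence of KPT-330 may account for the pattern, as would any difference in cell number or death between the cultures, which was not tested.

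The 12 libraries can be split into 4 groups of 3 in other ways, and 100 such splits were drawn with the real one included. For genes above 0, 2 splits gave an interaction count as large, and for genes below 0 and genes past the study's limit, 3 did. In each of the 99 other splits at least 1 group mixed libraries with and without KPT-330, so the effect of that drug entered the spread within groups, and 91 of them gave 0 genes above and 0 below. The share of under 0.05 set for these counts was therefore not a fair bound, and the splits do not decide whether chance is excluded for the interaction. The highest counts of the other splits were 2158, 2796 and 908 against the real 1565, 1288 and 148. A count of 908 is several times the real one and points to a structure of the samples: in that split the groups labelled DMSO, CS, KPT-330 and KPT-330+CS held 0, 3, 2 and 1 libraries with KPT-330. The splits for the pairwise comparisons do not decide about chance either. Each other split there mixes both treatments in both groups. The treatment difference thus entered the spread within groups, which favours low counts. For each of the 6 pairwise comparisons the 6 libraries give 10 splits, too few for a share under 0.05. In each, the real split was the 1 split with as many genes higher, lower and past the study's limit, and the highest other count was 0, or 1 for CS against KPT-330, beside real counts of 4815, 4631 and 588 for KPT-330, 731, 998 and 28 for CS, 5711, 5095 and 848 for the combination, 3925, 4400 and 520 for CS against KPT-330, 3836, 3475 and 166 for the combination against KPT-330, and 5081, 4216 and 583 against CS.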

How the results depend on the processing

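The GC corrections and the run without the lowest-GC-slope libraries were tests chosen after the results were seen. Of 285 gene results, 75 changed side of the threshold or sign in some alternative, and of 57 list results 17 did; all 17 lost their call with an estimated correlation, and 2 of them also with GC correction over all libraries. Of these 2, myeloid markers with CS also lost it with GC correction within groups and without the lowest-GC-slope libraries. The same call was lost without any single DMSO or CS library but DMSO replicate 2. Lists were not run with the stricter filter, DESeq2 itself, the likelihood ratio test, limma voom or the compared groups alone. The list calls with CS were thus not set against the fit that lowered the gene counts with CS most. Called genes did not turn sign under any alternative that tested them. Single genes were not followed under the likelihood ratio test, or where a filter removed them. Other than where the text says so the cause was not tested.

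Scaled by library size alone, genes lower were 2905 with KPT-330 and 3363 with the combination, and genes higher were 1365 with CS. DESeq2 size factors gave 660 genes lower with CS. With no filter, which tests more genes of low count, genes past the study's limit were 883 (KPT-330), 1348 (combination), 788 (CS against KPT-330), 275 (combination against KPT-330) and 958 (combination against CS). With the stricter filter, which tests fewer, they were 237, 371, 207, 67 and 229, with 8 for CS and 58 for the interaction. DESeq2 gave 15 for CS past that limit. With the compared groups alone, CS had 159 genes higher, 90 lower and 6 past the limit. GC correction within groups gave 1928 higher and 2722 lower with CS, 5379 lower in the combination against KPT-330, and 3457 higher and 3541 lower for the interaction; over all libraries it gave 1920 and 2643 with CS and 2959 lower for the interaction. Between 85.7% and 98.9% of the calls of each comparison were also called, with the same sign, after a GC correction. Without the lowest-GC-slope libraries every count stayed within 1.5 times.

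With replicate number as a block, CS had 477 genes higher, 559 lower and the interaction 1031 higher. Of 18 same-number pairs, 2 had deviations correlated over 0.1 (range -0.384 to 0.401), and 3 libraries best matched their own number. Correlations followed GC slopes, so pairing is undecided.

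Leaving out each library in turn gave 358 (CS replicate 2) to 876 (DMSO replicate 3) genes higher and 360 (CS replicate 3) to 1792 (DMSO replicate 1) lower with CS, and 885 (KPT-330 replicate 3) to 2639 (DMSO replicate 1) higher and 828 to 2072 lower for the interaction, for the same 2 libraries.

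Log2 fold changes that turned sign were of genes not called in the test reported. With KPT-330, GC correction over all libraries gave CDKN1A -0.048, BRCA1 0.023, CDC25B -0.11, RELB -0.42, CANX 0.074, TK1 -0.21 and XRCC3 -0.22. Of these CDC25B (adjusted p = 0.0154 by edgeR), RELB (adjusted p = 0.00146), CANX (adjusted p = 0.012), TK1 (adjusted p = 0.00126) and XRCC3 (adjusted p = 0.00132) passed the threshold there, with the sign turned. With GC correction within groups the same 5 passed with the sign of the test reported: CDC25B at 0.32, RELB at 0.30, TK1 at 0.41, XRCC3 at 0.45 and CANX at -0.063. The direction of these genes thus depended on the correction. DESeq2 and its size factors gave MDM2 -0.027. Library size alone gave SOX11 0.11, BRCA1 0.062 and CANX 0.095. Leaving out single libraries took MDM2 from -0.073 (DMSO replicate 1) to 0.091 (DMSO replicate 3), SOX11 from -0.10 (DMSO replicate 1) to 0.0083 (DMSO replicate 3) and CANX from -0.13 (DMSO replicate 1) to 0.0026 (DMSO replicate 3). With CS, library size alone gave CCNE2 0.044. The compared groups alone gave CCNE2 0.0099. GC correction over all libraries gave CCNE2 0.022. The run without the lowest-GC-slope libraries gave CCNE2 0.021. Leaving out single libraries took XPO1 from -0.0063 (DMSO replicate 1) to 0.17 (DMSO replicate 3), MDM2 from -0.14 (DMSO replicate 1) to 0.035 (DMSO replicate 3), CCND1 from -0.14 (CS replicate 3) to 0.34 (DMSO replicate 1) and CCNE2 from -0.14 (DMSO replicate 1) to 0.12 (DMSO replicate 3). With the combination, DESeq2 and its size factors gave MDM2 -0.011. Library size alone gave CDC25B 0.0051 and BRIP1 0.0045. Leaving out single libraries took MDM2 from -0.056 (DMSO replicate 1) to 0.12 (DMSO replicate 3), CCND1 from -0.074 (DMSO replicate 3) to 0.39 (DMSO replicate 1), CCNE2 from -0.0037 (DMSO replicate 1) to 0.25 (DMSO replicate 3) and POLD1 from -0.54 (KPT-330+CS replicate 1) to 0.22 (DMSO replicate 1).

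Genes printed as not passing the threshold passed it, with the same sign, in these alternatives. With KPT-330, library size alone gave CDKN1A 0.46, MDM2 0.16, CDC25B 0.45 and RELB 0.43. GC correction within groups gave CDKN1A 0.33, BRCA1 -0.10, CDC25B 0.32, RELB 0.30 and TK1 0.41. Leaving out DMSO replicate 1 gave CDKN1A 0.44, CCND1 0.63, BRCA1 -0.17, CDC25B 0.46, RELB 0.44 and TK1 0.66. GC correction over all libraries gave MDM2 0.16. With CS, GC correction within groups gave XPO1 0.08, SOX11 0.13, BRCA1 0.21, CHEK1 -0.12 and VLDLR 1.10. GC correction over all libraries gave XPO1 0.11, SOX11 0.12, BRCA1 0.23, CHEK1 -0.10 and VLDLR 1.12. Library size alone gave SOX11 0.19, BRCA1 0.27 and VLDLR 1.16. Leaving out DMSO replicate 1 gave MYC 0.25 and CHEK1 -0.19. Leaving out the lowest-GC-slope libraries gave BRCA1 0.24. Leaving out DMSO replicate 3 gave BRCA1 0.30. Leaving out CS replicate 2 gave VLDLR 1.31. With the combination, library size alone gave CDKN1A 0.47, MDM2 0.21, SOX11 0.33, CCNE2 0.30 and NFKB2 0.55. GC correction within groups gave CDKN1A 0.29, SOX11 0.14, CDC25B -0.16, BRIP1 -0.18 and NFKB2 0.38. Leaving out DMSO replicate 1 gave CDKN1A 0.41, BRIP1 -0.27 and NFKB2 0.53. Leaving out KPT-330+CS replicate 3 gave CDKN1A 0.40, BRIP1 -0.25 and NFKB2 0.48. The stricter filter gave SOX11 0.17. Limma voom gave SOX11 0.14. Leaving out the lowest-GC-slope libraries gave SOX11 0.18 and BRIP1 -0.20. The compared groups alone gave SOX11 0.17. Leaving out DMSO replicate 3 gave SOX11 0.21. GC correction over all libraries gave POLD1 -0.47, CDC25B -0.34, BRIP1 -0.14 and NFKB2 0.17. In the interaction, CHEK1 was at -0.32 with library size alone, -0.28 with GC correction within groups, -0.42 with GC correction over all libraries, -0.34 without the lowest-GC-slope libraries, -0.34 without DMSO replicate 3 and -0.32 without KPT-330+CS replicate 3.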

Other observations

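In this part the test of reads moved between copies, the test of another clone and the FOXO list were chosen after the results were seen, as were the genes named here. Light chains of immunoglobulin moved apart with the drugs. Reads summed over the lambda constant genes were at 166 ± 53.4 CPM in DMSO, 67.0 ± 15.9 in CS, 247 ± 15.3 in KPT-330 and 46.4 ± 6.02 in the combination (SD, n = 3), while the kappa constant gene was at 1627 ± 158, 1538 ± 88.6, 1700 ± 114 and 1440 ± 62.1 CPM. In the mitochondria, both ribosomal RNA genes summed to 12379 ± 1337 CPM in DMSO and 24640 ± 1557 in the combination. MT-RNR2 rose by 1.03 ± 0.08 on the log2 scale there (adjusted p = 1.94e-07 by edgeR), in libraries selected for poly(A).

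Of the lists not described above, nuclear export and import genes were lower with CS for 6 of 22 with 0 higher by edgeR (7 lower adjusted over the list alone; median -0.13, camera adjusted p = 0.000198), and hypoxia and glycolysis genes for 7 of 26 with 2 higher (11 and 3 adjusted over the list alone; median -0.23, camera adjusted p = 0.000739). With KPT-330, base excision repair genes were higher for 12 of 21 and lower for 4, also adjusted over the list alone (median 0.45, camera adjusted p = 0.163), and interferon-stimulated genes were lower for 10 of 26 and higher for 4, also adjusted over the list alone (median -0.17, camera adjusted p = 0.0355, and adjusted p = 0.0898 with an estimated correlation). With both drugs, replication-dependent histone genes were lower for 24 of 48 and higher for 3, also adjusted over the list alone (median -0.60, camera adjusted p = 0.000562, and adjusted p = 0.271 with an estimated correlation). With both drugs camera's adjusted p was 0.666 for autophagy and lysosome genes, 0.8 for BCL2 family genes, 0.995 for choline genes, 0.637 for mantle cell lymphoma genes, 0.76 for prostaglandin genes, 0.941 for plasma cell genes, 0.121 for myeloid markers and 0.33 for fibroblast and endothelial markers. Mitochondrially encoded protein genes were higher with CS for 2 of 13 with 0 lower by edgeR (5 higher adjusted over the list alone; median 0.13, camera adjusted p = 0.00215, and adjusted p = 0.541 with an estimated correlation).

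Lambda constant and joining genes were lower in the combination than in KPT-330 alone, with a median log2 change of -3.02 over 9 tested genes (-1.98 to -4.76). Reads moved between near-identical copies would leave the sum over the constant genes in place, and that sum changed by -2.42. A GC trend between libraries would shrink the median once removed, and it was then -2.75. Fewer cells of another clone with a rearranged lambda chain would lower the variable genes too, and their sum changed by 0.11. These values argue against the 3 explanations as the whole cause, and lower transcription of an unrearranged lambda locus may account for the pattern, as a hypothesis that was not tested.

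A hypothesis from the named genes was that targets of FOXO transcription factors rose with both drugs, since FBXO32 (4.87 ± 0.24), TP53INP1 (4.31 ± 0.17), TSC22D3 (2.79 ± 0.07), KLHL24 (2.73 ± 0.07), BMF (2.61 ± 0.11), DDIT4 (0.90 ± 0.10) and GABARAPL1 (0.52 ± 0.12) did. A list of 24 other tested targets had a median log2 fold change of 0.39, with 15 higher and 4 lower. Camera's p, not adjusted, was 0.00525 at the preset correlation and 0.0741 with an estimated correlation, so the list may have risen with these genes only as far as the preset test goes.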
